A study of Homo sapiens with 12 samples.

How the data were processed

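Sorted neutrophil populations of human bone marrow were compared by RNA sequencing. Per the labels' protocols, cells were sorted by flow cytometry from fresh marrow into TRIzol LS, RNA was purified on Direct-zol columns and measured on a TapeStation, and libraries followed the Smart-Seq2 protocol. The authors deposited a table of raw read counts per NCBI gene ID with 1 column per library, and the values were whole numbers with totals that differed between libraries, as raw counts do. Per the submitters' processing notes, FastQC 0.11.7, featureCounts 1.22.2 and edgeR 1.30.5 were used with the hg38 build. The aligner, the annotation version, the strand setting and any filter on reads were not given in the sources used here. Smart-Seq2 libraries do not mark strand in the original protocol, and since the counting setting is not stated, values of antisense and overlapping genes are uncertain. The same holds for near-identical copies such as FCGR3A and FCGR3B, DEFA1 and its copies, the hemoglobin alpha genes, NCF1 and its pseudogenes, and ribosomal protein genes with processed pseudogenes.

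Libraries were assigned to populations by their titles and labels. The 12 columns were matched to samples by title. In 1 column name the CD117 status is missing, and it was matched to N1 3 because no other CD71-positive title carries that number. The CD117 status of N1 3 therefore rests on that title. Columns of per-sample values not used numbered 0. Gene symbols and coordinates came from a RefSeq gene table of GRCh38.p14, an assembly of the same build as hg38. Of 28395 gene IDs, 27745 matched a symbol and 650 did not, and these held at most 0.1135% of the counts of any library. They were kept in library sizes and tests. XIST, Y-linked genes, immunoglobulin and T cell receptor segments and clone identifiers were left out of the named genes.

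Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 17145 genes, and libraries were scaled by TMM, with factors from 0.654 to 1.45. One quasi-likelihood fit with robust estimation held all 12 libraries with 1 coefficient per population and 8 residual degrees of freedom, because the labels give no donor, day or batch to block on. Its common biological coefficient of variation was 0.821. The 4 contrasts were taken from that fit (eNeP with N1, N1 with N2, N2 with mature, eNeP with mature), together with a test over 3 coefficients for any difference among populations. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The SE of a log2 fold change is its size divided by the square root of its F statistic. Levels are CPM scaled by the TMM factors, and SDs run over the 3 libraries of a population. Sums over a gene list are CPM of the whole library total without TMM factors.

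Gene lists, 34 in number and written from textbook knowledge, were tested with camera in limma 3.58.1 on log CPM (prior count 2) with the correlation between genes estimated from the data, and p-values were adjusted over all 136 list tests. Counts of called members are given over all genes tested and adjusted over the list alone. Where a population had 0 counts of a gene, a fold was computed against a floor of 3 counts over the group and is a lower bound. With 1 to 3 counts, the ratio has an exact Poisson interval at the 95% level. PCR copies without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. The principal component analysis used log CPM of the 500 most variable genes.

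Genes were named by a fixed rule. In every comparison these were KIT, TFRC, FCGR3A, FCGR3B, CEACAM8, CD34, MPO, ELANE, LTF, CXCR2, MKI67, CEBPA, CEBPE, GFI1 and MYC. To these came the 6 called genes with the highest and the 6 with the lowest log2 fold change that had a mean of at least 20 CPM in the higher group and no overlap of single libraries. From each list came up to 3 called members with the largest change in the direction of most called members and up to 2 called the other way. Of the genes so found, the text names those it can describe, and some are not reported here.

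The test was checked on simulated counts for the comparison of eNeP with N1, drawn from the means and library sizes of these data over 15713 genes, of which 200 were changed. The changed genes were drawn only from genes above a minimum mean CPM, and the simulated spread followed the trend over abundance. The test recovered 26.87% of the genes changed 4-fold, 94.03% of those changed 16-fold and 100% of those changed 64-fold. Recovery of scarcer or more variable genes was not simulated and can be lower. Of the calls of the test 2% were false, and a contrast without change gave 0 calls. A planted list reached an adjusted p of 0.0003305 by camera and 0 other lists were called. The simulated genes were given no correlation with each other, which camera estimates in the real data. The check also covered the lists of eNeP with N1 and not the list tests of all comparisons. It therefore cannot show how often camera finds or falsely calls lists of correlated genes.

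The alternatives were DESeq2 size factors in place of TMM, TMM without mitochondrial, ribosomal protein, hemoglobin and azurophil genes, no filter on low counts, a filter of at least 10 CPM in 3 libraries, a fit without robust estimation, and a factor for runs of consecutive library numbers, in which eNeP 82 forms a run of its own. Further ones were a minimum fold of 2, a fit of only the 2 groups compared, DESeq2 1.42.0, limma-voom, camera with a preset correlation of 0.01, fry, and each library left out in turn. A fit without both eNeP 82 and N1 3 and a fit with a curve on transcript GC content taken out of each library were added after seeing the data.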

Results

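Neutrophils are made in the bone marrow from dividing progenitors that fill their granules in a set order before they stop dividing and mature. The series was made to describe an early progenitor restricted to that lineage, recognised in human marrow by the surface antigens CD117 (the stem cell factor receptor, gene KIT) and CD71 (the transferrin receptor, gene TFRC). RNA was measured with Smart-Seq2, a full-length cDNA method for low input, in 4 populations sorted by flow cytometry. These were eNeP (positive for CD71 and CD117), N1 (positive for CD71, negative for CD117), N2 (negative for CD16 and CD71) and mature cells (positive for CD16, the low-affinity Fc gamma receptor III). Each population had 3 libraries, which are called here by the number in their titles: eNeP 7, 11 and 82, N1 3, 6 and 10, N2 2, 5 and 9, and mature 1, 4 and 8.

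The total gene count was 19011546 in eNeP 7, 7055500 in eNeP 11 and 14228557 in eNeP 82. It was 26524304 in N1 3, 18884893 in N1 6 and 16098122 in N1 10. The N2 libraries held 19720162 (N2 2), 70495466 (N2 5) and 32173946 (N2 9) counts, and the mature libraries 15816966 (mature 1), 7639071 (mature 4) and 8359471 (mature 8). Between 14845 genes (N2 2) and 23105 genes (eNeP 82) had at least 1 count. The labels name no donor, culture, day or batch, so all p-values measure only the spread between these 12 libraries, which may be technical. The number 82 lies far outside the 1 to 11 of the other libraries and the labels do not say why, so whether eNeP 82 was prepared alongside them is not known. Levels are given as TMM-normalised CPM, mean ± SD of 3 libraries, and differences as log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Only sums over a gene list are CPM before TMM scaling.

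The transcripts of the sorting antigens were examined first, since they bear on the labels. FCGR3B, which encodes the CD16 of neutrophils (gene ID 2215, chromosome 1, 161623196 to 161631963 in GRCh38), was at 0.861 ± 0.304 CPM in eNeP, 1.72 ± 0.405 in N1, 23.85 ± 18.0 in N2 and 2104 ± 2258 in mature cells (n = 3 each; adjusted p = 1.58e-06 among the 4 populations). FCGR3A, its near-identical copy, was at 158 ± 90.8 CPM in mature cells and 1.96 CPM in N2, but reads of the pair could have been split between both genes, so the value of each is uncertain. TFRC (gene ID 7037, chromosome 3, 196049284 to 196082090) stood at 38.3 ± 21.3 CPM in eNeP and 42.2 ± 5.35 in N1, the CD71-positive sorts, against 17.5 ± 4.40 in N2 and 8.83 ± 3.51 in mature cells (adjusted p = 0.019). KIT (gene ID 3815, chromosome 4, 54657957 to 54740715) was scarce everywhere, at 6.86 ± 6.42 CPM in eNeP, 2.355 ± 1.59 in N1, 0.462 ± 0.244 in N2 and 1.425 ± 0.802 in mature cells (adjusted p = 0.0449). Between eNeP and N1, the sorts that CD117 separated, the KIT transcript differed by a log2 fold change of 1.54 ± 0.97, which did not exceed the spread between libraries (adjusted p = 0.828). KIT in N1 3 (3.207 CPM) and N1 6 (3.341 CPM) lay above KIT in eNeP 11 (1.533 CPM). Its log2 fold change ranged from 0.27 to 1.98 over the alternatives run for single genes, with an adjusted p from 0.396 to 1. CEACAM8, the granulocyte antigen CD66b (gene ID 1088, chromosome 19, 42580243 to 42594924), was at 816 ± 386, 3544 ± 506, 3457 ± 1613 and 41.2 ± 34.3 CPM in eNeP, N1, N2 and mature cells (adjusted p = 4.42e-05).

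**Figure D1:**
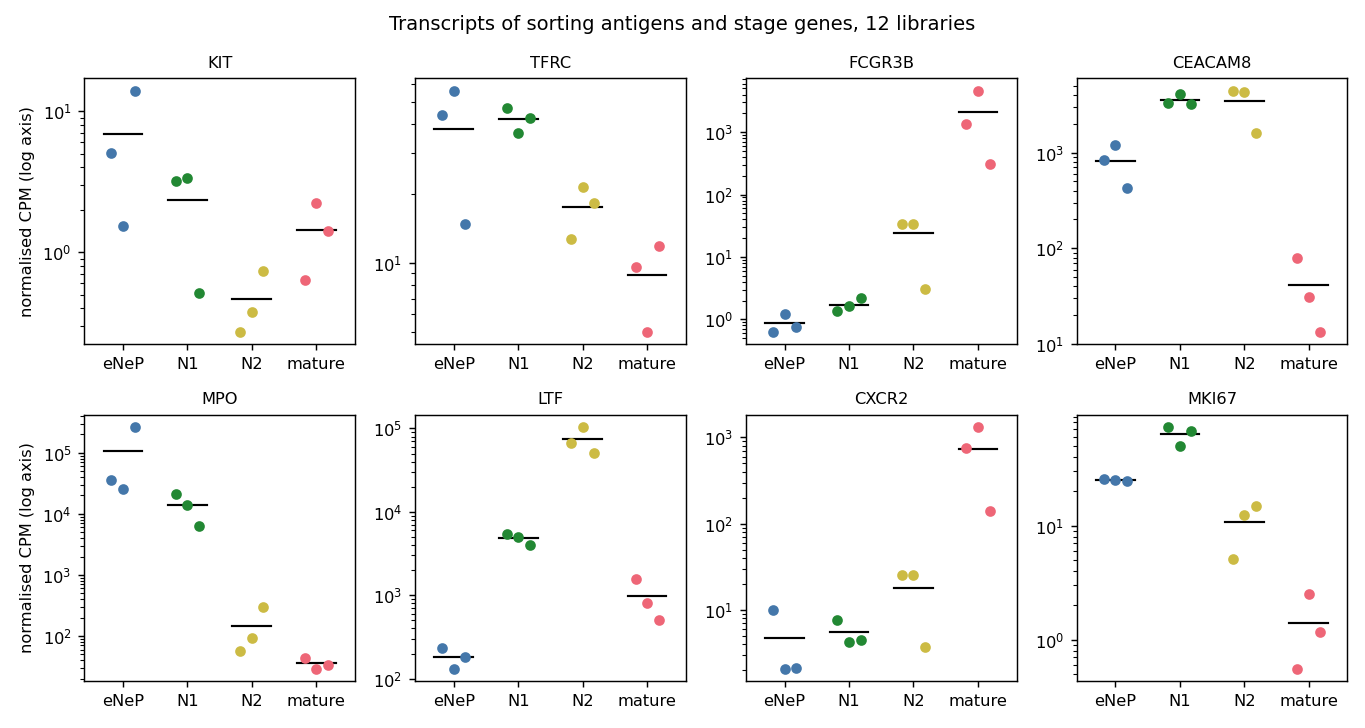
Normalised CPM (log axis) of 8 marker genes in each of the 12 libraries, grouped by population, with a line at the mean of 3. The highest mean of MPO was in eNeP, that of LTF in N2, and those of FCGR3B and CXCR2 in mature cells.

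A principal component analysis of the 500 most variable genes separated mature cells and N2 from eNeP and N1 along component 1, which held 72.0% of the variance. On that axis N2 lay between 16.84 and 38.38 and mature cells between 72.04 and 91.14, while eNeP and N1 both lay below 0. Component 2, with 12.5% of the variance, separated eNeP (14.6 to 27.18) from N1 (−14.94 to −5.114). Across genes within pairs of libraries, Pearson's r of log CPM was 0.906 to 0.9385 inside N1 and 0.9175 to 0.939 inside N2. It was lower inside eNeP (0.783 to 0.864) and inside mature cells (0.810 to 0.875), and a pair of eNeP and N1 libraries reached 0.766 to 0.906. Genes are not independent replicates, so these coefficients describe the libraries only. Transcripts encoded by the mitochondrial genome took 12 ± 2.88% of the counts in eNeP, 6.74 ± 1.01% in N1, 2.90 ± 0.480% in N2 and 1.17 ± 0.645% in mature cells. Ribosomal protein genes took 3.92 ± 0.614%, 2.30 ± 0.455%, 0.7025 ± 0.205% and 0.354 ± 0.215% in the same order.

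**Figure D2:**
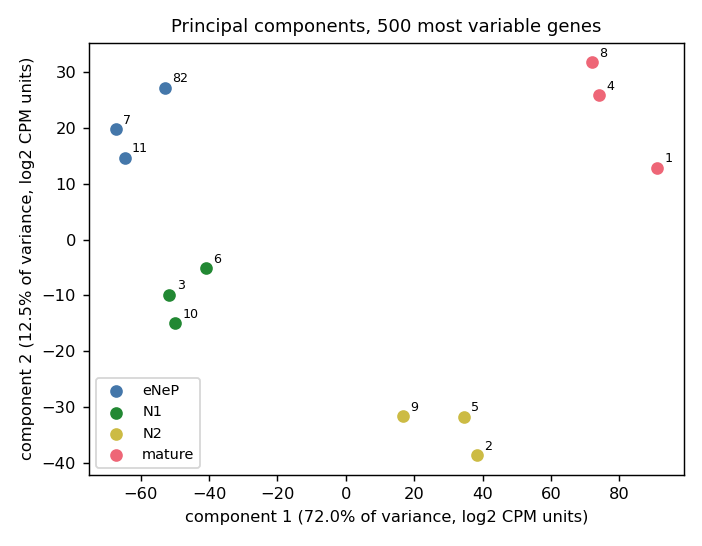
Components 1 (72.0% of variance) and 2 (12.5%) of a principal component analysis of log CPM of the 500 most variable genes, with 1 point per library labelled by its number and coloured by population. Mature libraries lay at 72.04 to 91.14 on component 1, and eNeP and N1 parted on component 2.

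The comparison of eNeP with N1 asks what accompanies CD117 among CD71-positive cells. Of the gene lists, that of the specific (secondary) granules held the most called genes, all lower in eNeP. Lactoferrin, LTF (gene ID 4057, chromosome 3, 46435645 to 46485234), was at 181 ± 49.9 CPM in eNeP and 4843 ± 751 in N1, a log2 fold change of −4.74 ± 0.57 (adjusted p = 0.0012, n = 3 each). The vitamin B12 carrier TCN1 was at 6.34 ± 3.245 against 507 ± 44.2 CPM (−6.31 ± 0.70, adjusted p = 0.000637) and the iron-siderophore binder LCN2 at 67.6 ± 23.35 against 3370 ± 473 CPM (−5.64 ± 0.72). CHI3L1 was lower by −5.37 ± 0.66, and by −6.09 without eNeP 11. Of 20 specific granule genes, 8 were lower in eNeP and 0 higher, and 18 were lower when adjusted over the list alone, with a median log2 fold change of −3.98. In the gelatinase granule and secretory vesicle list, 3 of 16 genes were lower (5 adjusted over the list alone): ficolin-1 (FCN1, −5.73 ± 0.64, 45.2 against 2401 CPM), properdin (CFP, −4.51 ± 0.61) and the membrane protease ADAM8 (−3.85 ± 0.52). Among 26 receptors and effectors of mature neutrophils, 1 was lower, the calprotectin subunit S100A8 (−5.02 ± 0.68, 276 against 8938 CPM), with 7 adjusted over the list alone. Among 18 chemotaxis and retention receptors, 2 were lower, the integrin subunits ITGAM (−4.16 ± 0.56, adjusted p = 0.00211) and ITGB2 (−3.10 ± 0.53, adjusted p = 0.0218), with 6 adjusted over the list alone. The call of ITGB2 ended without eNeP 7 (adjusted p = 0.162), eNeP 11 (0.0667), eNeP 82 (0.0669) or N1 6 (0.058), without both eNeP 82 and N1 3 (0.241) and with the GC curve (0.111).

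Of 12 azurophil (primary) granule genes, made first in the lineage, 9 had a positive log2 fold change of eNeP over N1 and 3 a negative one, and 0 passed the test. MPO, myeloperoxidase (gene ID 4353, chromosome 17, 58269855 to 58280935), was at 108100 ± 134000 CPM in eNeP and 13790 ± 7303 in N1, a log2 fold change of 2.97 ± 0.83 (adjusted p = 0.315). Most of that SD came from eNeP 82, with 262700 CPM against 35990 in eNeP 7 and 25630 in eNeP 11. Neutrophil elastase, ELANE, differed by 3.36 ± 0.94 (adjusted p = 0.315) and was called with DESeq2 (adjusted p = 0.0101). Adjusted over the list alone, 6 azurophil genes were higher and 1 lower (median log2 fold change 1.76). Among 18 genes of granulocyte-monocyte progenitors 0 were called over all genes and 4 were higher adjusted over the list alone (median 1.41), and among 20 stem and early progenitor genes 0 were called either way (median 1.23). CD34, the stem cell antigen, was at 2.32 CPM in eNeP and 1.01 in N1 (adjusted p = 0.892). The proliferation marker MKI67 stood at 25.15 ± 0.520 CPM in eNeP and 63.1 ± 12.2 in N1 (−1.33 ± 0.56, adjusted p = 0.653), and 0 of 35 DNA replication genes and 0 of 30 mitosis genes were called (medians −0.64 and −0.97). No member of the 74 ribosomal protein genes passed (median 0.97), nor of the 13 mitochondrially encoded transcripts (median 0.95), whose share of counts was 12 ± 2.88% in eNeP and 6.74 ± 1.01% in N1. Of 12 eosinophil markers 10 had a lower log2 level in eNeP than in N1 (0 called, 3 lower adjusted over the list alone, median −1.77), with a summed level before TMM scaling of 8486 to 16100 CPM in eNeP and 16540 to 36430 CPM in N1. That list was not called by camera (adjusted p = 0.0664), but it was with TMM without the abundant gene classes, without eNeP 82 and without N1 3. It was also called by fry (adjusted p = 0.02). CEACAM8 differed by −2.12 ± 0.62 (adjusted p = 0.368) and was called with DESeq2 (−1.96, adjusted p = 0.0366).

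In all, edgeR called 32 genes lower in eNeP than in N1 and 0 higher among 17145 tested. At an unadjusted p under 0.05 there were 692 lower and 448 higher, and the genes called higher numbered 65 with DESeq2, 7 with limma-voom, 7 with the run of library numbers as a factor, 5 with no filter on low counts and 2 without N1 3. The smallest called difference was 2.49 on the log2 scale, and in simulated data of this design 26.87% of 4-fold changes were recovered among genes above a minimum mean CPM. The count was 67 with the run factor, 11 without eNeP 7, 19 without eNeP 11, 14 without eNeP 82, 21 without N1 3 and 20 without N1 6. With the run factor eNeP 82 is alone in its run, so that fit sets only eNeP 7 and 11 against N1. For whole lists, limma's camera with the correlation estimated from the data called specific granule proteins (adjusted p = 0.0371) and late granulocyte transcription factors (adjusted p = 0.0371), the latter with 0 of 18 members called (1 lower adjusted over the list alone, median −0.88). The specific granule call ended without eNeP 7 (adjusted p = 0.0601), eNeP 11 (0.0707) or N1 6 (0.0584), and the transcription factor call without eNeP 7 (0.0601), eNeP 11 (0.0913), eNeP 82 (0.0588), N1 6 (0.0584) or N1 10 (0.0643). Of the 34 lists, camera with a preset correlation called 21, 18, 21 and 23 in the 4 comparisons (eNeP with N1, N1 with N2, N2 with mature, eNeP with mature), and with the estimated correlation 2, 6, 4 and 7 of these held. Rotation testing with fry, which asks whether a list moves one way without setting it against other genes, called 10, 15, 18 and 23. All 19 calls with the estimated correlation ended with the run of library numbers as a factor (adjusted p from 0.0996 to 0.217) and without both eNeP 82 and N1 3 (0.056 to 0.093), an alternative chosen after seeing the data.

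**Figure D3:**
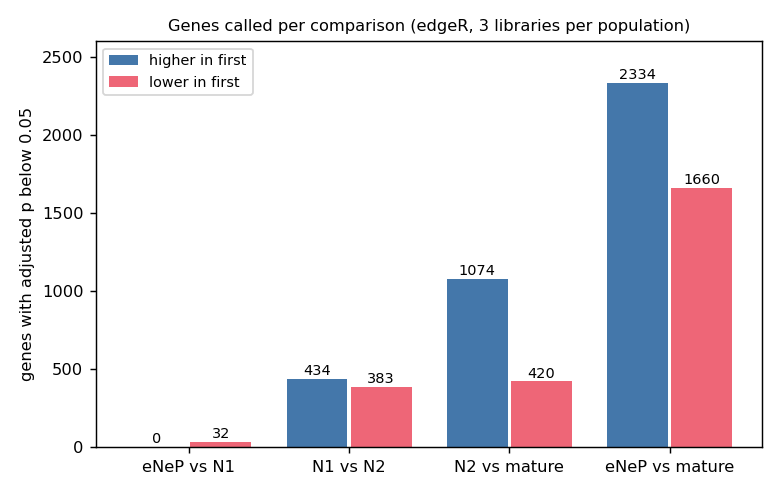
Number of genes (adjusted p under 0.05 of 17145 tested) higher and lower in the first population of each of the 4 comparisons. The bars stand at 0 and 32 for eNeP with N1, 434 and 383 for N1 with N2, 1074 and 420 for N2 with mature cells, and 2334 and 1660 for eNeP with mature cells.

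The comparison of N1 with N2 follows the loss of CD71. Most azurophil granule genes were higher in N1, and some genes of later granules and of receptors were higher in N2. The defensin DEFA4 was at 11360 ± 1779 CPM in N1 and 76.9 ± 13.7 in N2 (log2 fold change 7.21 ± 0.53, adjusted p = 2.87e-06, n = 3 each). Cathepsin G, CTSG (gene ID 1511, chromosome 14, 24573518 to 24576250), was higher by 8.80 ± 0.98 (7.74 without N1 3), MPO by 6.55 ± 0.99 (7.53 without N2 9) and ELANE by 8.16 ± 1.23 (7.35 without N1 3). Proteinase 3, PRTN3, had 0 counts in N2 and 6.31 CPM in N1, at least 205.6-fold higher against a floor of 3 counts over the group. The bound was 96.94 without N1 3, 105.2 without N2 5 and 131.4 without N2 9. Of 12 azurophil genes 8 were higher in N1 and 0 lower (11 higher adjusted over the list alone, median 6.88), and camera called the list (adjusted p = 0.0371).

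Lactoferrin continued to differ. LTF was at 73700 ± 27040 CPM in N2 (−3.93 ± 0.55, adjusted p = 0.000782), and of the 20 genes 9 were lower in N1 and 1 higher (12 and 1 adjusted over the list alone), with haptoglobin (HP, −5.01 ± 0.92) and orosomucoid (ORM1, −4.89 ± 0.58) among the lower. The list as a whole was not called (adjusted p = 0.106). In the gelatinase and secretory list 10 of 16 genes were lower in N1 (11 adjusted over the list alone, median −2.47, camera adjusted p = 0.0489). These included the gelatinase MMP9, at 51.8 ± 59.9 CPM in N1 and 9769 ± 5175 in N2 (−7.56 ± 1.03; −9.12 without N1 3), the formyl peptide receptor FPR1, at 6.14 ± 1.29 and 569 ± 162 CPM (−6.53 ± 0.55, adjusted p = 1.09e-05), and the metal transporter SLC11A1 (−5.48 ± 1.03). Of 26 receptors and effectors of mature neutrophils, 10 were lower in N1 and 0 higher (16 and 1 adjusted over the list alone, median −1.96, camera adjusted p = 0.0429), such as S100A12 (−7.81 ± 1.0, 134 against 30060 CPM; −8.96 without N1 3) and CMTM2 (−6.19 ± 0.80; −5.56 without N2 2). Of 18 chemotaxis and retention receptors 6 were lower (11 lower and 1 higher adjusted over the list alone, median −1.98, camera adjusted p = 0.0431), including ITGAM (−2.82 ± 0.53) and the complement receptor C5AR1 (−7.135 ± 0.75; −6.37 without N2 5). The carbonic anhydrase CA4 (1.01 against 262 CPM, −8.00 ± 1.0) and the connexin GJB6 (1.03 against 203 CPM, −7.63 ± 0.95; −8.33 without N1 10) had some of the lowest ratios. FCGR3B was lower in N1 by −3.79 ± 0.90 (adjusted p = 0.0215), a call that ended without N1 3 (0.0834), N1 6 (0.0531), N2 2 (0.0691) or N2 5 (0.0669), and without both eNeP 82 and N1 3 (0.112). CEACAM8 (0.04 ± 0.60, adjusted p = 0.984), TFRC (1.27 ± 0.55, adjusted p = 0.223) and CXCR2 (−1.73, adjusted p = 0.272) did not pass.

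Of 35 DNA replication genes, 23 were higher and 0 lower (35 higher adjusted over the list alone, median 3.20, camera adjusted p = 0.0489), among them the replicative helicase subunits MCM2 (99.9 ± 40.6 against 6.08 ± 5.365 CPM, 4.03 ± 0.78; 4.87 without N2 9) and MCM4 (3.94 ± 0.72). Of 30 mitosis genes 3 were higher (14 adjusted over the list alone, median 1.89, camera adjusted p = 0.213). MKI67 was higher by 2.54 ± 0.58 (adjusted p = 0.0171), which ended without N1 3 (0.0689), N2 2 (0.1) or N2 5 (0.0604), without both eNeP 82 and N1 3 (0.0727) and with the GC curve (0.0529). Of 18 granulocyte-monocyte progenitor genes 12 were higher in N1 and 0 lower (12 and 1 adjusted over the list alone, median 3.22, camera adjusted p = 0.128), including the transcription factor MYB (3.18 ± 0.60). Of 18 late granulocyte transcription factors 6 were lower in N1 (9 adjusted over the list alone, median −1.59, camera adjusted p = 0.0312), JUNB among them (−3.17 ± 0.66). JUNB is also a dissociation and stress response gene, and that list summed before TMM scaling to 2274 to 2952 CPM in N1 and 3520 to 5765 CPM in N2. Of its 15 tested genes 4 were lower in N1 and 2 higher (6 and 4 adjusted over the list alone, camera adjusted p = 0.635). CEBPE (0.44, adjusted p = 0.737), CEBPA (−0.06) and GFI1 (−0.58, adjusted p = 0.747), regulators of granulopoiesis, did not differ beyond their spread. Of 12 eosinophil markers tested, 4 were higher in N1 and 0 lower (5 higher and 2 lower adjusted over the list alone, median 0.60, camera adjusted p = 0.385). Before TMM scaling their summed level was 16540, 35620 and 36430 CPM in N1 3, 6 and 10, against 983, 951 and 4506 CPM in N2 2, 5 and 9. RNASE3 was higher by 3.50 ± 0.60 and RNASE2 by 3.27, ribonucleases that neutrophil precursors are also known to make. PRG2, the major basic protein gene, was higher by 3.965 (adjusted p = 0.0419; 7.04 without N2 9), a call that ended without N1 6 (0.0697), N1 10 (0.0726), N2 2 (0.13) or N2 5 (0.124). It also ended under both other scalings (0.0766 and 0.0803), with only the 2 groups in the fit (0.0962), without both eNeP 82 and N1 3 (0.0637) and with the GC curve (0.114).

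In total 817 genes differed between N1 and N2, 434 higher and 383 lower in N1. The balance turned to 362 higher and 479 lower with TMM factors computed without the abundant gene classes, and the total was 2126 with DESeq2, 1352 with limma-voom and 1840 (965 higher and 875 lower) with the run of library numbers as a factor. The count was 368 without N1 3, 532 without N1 6, 373 without N2 2 and 389 without N2 5. All 6 list calls ended without N1 6, N2 2 or N2 9, with an adjusted p from 0.0529 to 0.0862. The gelatinase and DNA replication calls also ended without any other single library of the 2 groups (N1 3, N1 10 and N2 5: 0.0522, 0.0784 and 0.0509 for gelatinase, 0.0539, 0.094 and 0.0811 for DNA replication) and with DESeq2 size factors (0.0555 and 0.0592), and that of DNA replication with TMM without the abundant gene classes (0.0658).

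**Figure D4:**
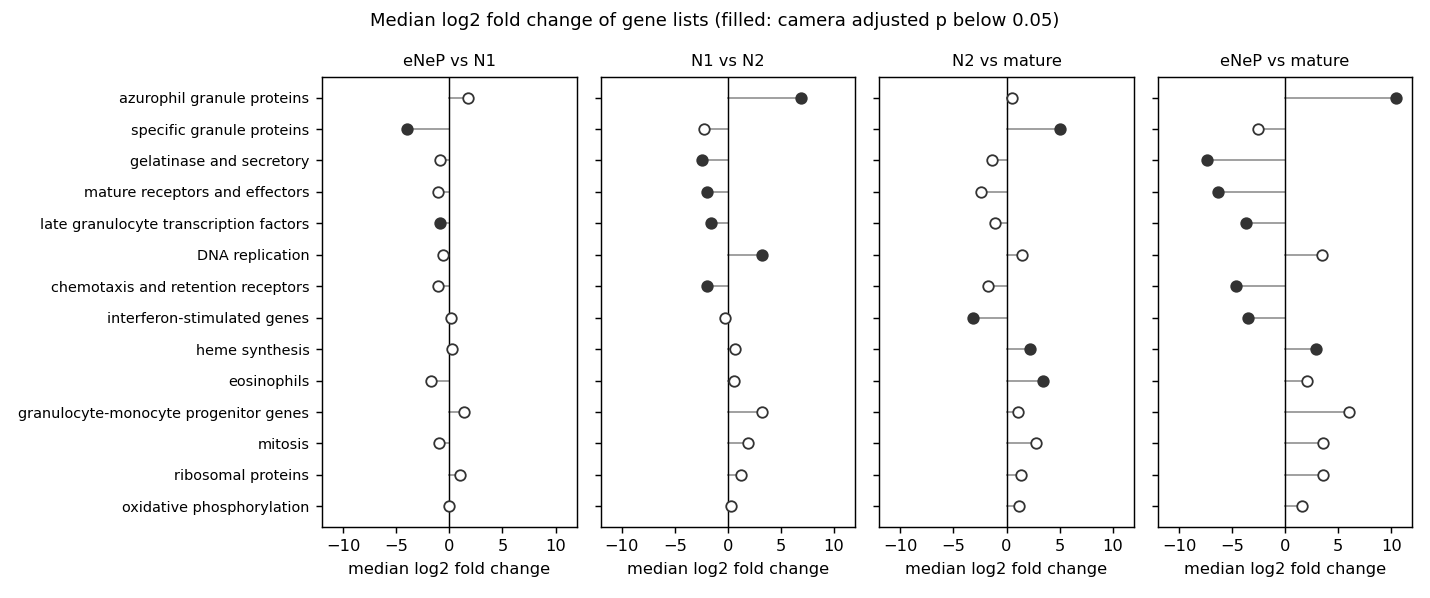
Median log2 fold change of 14 gene lists in each of the 4 comparisons, where filled points mark an adjusted p under 0.05 in camera with the estimated correlation. Azurophil genes had a median of 6.88 for N1 over N2, and specific granule genes 5.02 for N2 over mature cells.

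The comparison of N2 with mature cells spans the gain of CD16. Most specific granule genes were higher in N2, and most interferon-stimulated genes and some genes of secretory vesicles and receptors were higher in mature cells. LTF was at 969 ± 555 CPM in mature cells, lower than in N2 by a log2 fold change of 6.25 ± 0.61 (adjusted p = 9.33e-05, n = 3 each; 6.87 without mature 1), and CEACAM8 differed by 6.39 ± 0.76 (7.35 without mature 1). Of 20 specific granule genes 18 were higher in N2 and 0 lower (20 adjusted over the list alone, median 5.02, camera adjusted p = 0.0451). Of 12 azurophil genes 2 were higher in N2 and 1 lower, with the same numbers adjusted over the list alone, and the median of 0.48 became 0.23 with 2 genes that had no count in a group set to their bound. DEFA4 was higher in N2 by 2.24 ± 0.43 and serglycin, SRGN, a proteoglycan of granule storage, was lower by −2.83 ± 0.59. MPO (2.05 ± 0.81, adjusted p = 0.117) did not pass. It was called with the run of library numbers as a factor (2.03, adjusted p = 0.0307) and without both eNeP 82 and N1 3 (0.046).

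In mature cells, alkaline phosphatase ALPL was at 650 ± 389 CPM against 0.589 ± 0.315 in N2 (−10.04 ± 1.21, adjusted p = 0.000241), the water and glycerol channel AQP9 at 655 ± 281 against 2.67 ± 0.775 CPM (−7.94 ± 0.94) and the neprilysin gene MME at 257 ± 229 against 0.262 ± 0.127 CPM (−10.00; −8.90 without mature 1). The pantetheinase VNN2 was lower in N2 by −5.12 ± 0.80. The chemokine CXCL8 was at 1587 ± 1379 CPM in mature cells and 9.62 ± 9.395 in N2 (−7.37 ± 1.05; −8.48 without N2 2 and −6.34 without mature 1). FCGR3B (−6.46 ± 1.01; −5.11 without mature 4 and −7.07 without mature 8), CXCR2 (−5.34 ± 0.94; −4.59 without mature 4) and FPR1 (−3.05 ± 0.47) were also lower in N2. By list, 6 of 16 gelatinase and secretory genes were lower in N2 (8 lower and 1 higher adjusted over the list alone, median −1.38, camera adjusted p = 0.385). So were 10 of 26 receptors and effectors of mature neutrophils (16 adjusted over the list alone, median −2.44, camera adjusted p = 0.205) and 5 of 18 chemotaxis receptors (10 lower and 1 higher adjusted over the list alone, median −1.715, camera adjusted p = 0.341). Among 20 interferon-stimulated genes 14 were lower in N2 and 0 higher (16 adjusted over the list alone, median −3.16, camera adjusted p = 0.0371). IFIT3 was at 2.05 ± 0.254 CPM in N2 and 107 ± 16.75 in mature cells (−5.70 ± 0.58, adjusted p = 9.33e-05) and IFIT1 at 0.811 ± 0.246 and 46.7 ± 14.0 CPM (−5.85 ± 0.76), both antiviral proteins induced by interferon. The dissociation and stress response list, before TMM scaling, summed to 3520 to 5765 CPM in N2 and 8081 to 27480 CPM in mature cells. Whether handling raised genes such as CXCL8 in mature cells was not tested.

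Of the regulators of granulopoiesis, CEBPE (423 ± 219 against 12.2 ± 2.33 CPM, 5.12 ± 0.66, adjusted p = 0.000371) and GFI1 (5.33 ± 0.93; 4.44 without N2 9) were higher in N2, while CEBPA (0.99, adjusted p = 0.267) and MYC (0.38, adjusted p = 0.766) did not differ beyond their spread. Of 30 mitosis genes 14 were higher in N2 (16 adjusted over the list alone, median 2.74, camera adjusted p = 0.213), with MKI67 at 2.98 ± 0.61 (3.69 without mature 4). Of 35 DNA replication genes 6 were higher (10 adjusted over the list alone, median 1.46), of 52 oxidative phosphorylation genes 14 (23 adjusted over the list alone, median 1.19) and of 74 ribosomal protein genes 16 (27 adjusted over the list alone, median 1.32), none of which was called as a list (adjusted p = 0.343, 0.246 and 0.343). NDUFA9, a subunit of respiratory complex I, was higher by 3.64 ± 0.54, RPL5 by 3.49 ± 0.54 and the mitochondrially encoded MT-CO1 by 3.22 ± 0.55. Reads of ribosomal protein genes can also come from their many processed pseudogenes. Of 8 heme synthesis genes 4 were higher in N2 (5 adjusted over the list alone, median 2.25, camera adjusted p = 0.0371), with UROS at 3.93 ± 0.56. Of 12 eosinophil markers 7 were higher in N2 and 0 lower (7 adjusted over the list alone, median 3.45, camera adjusted p = 0.0414). RNASE2 was higher by 5.59 ± 0.58, while EPX, eosinophil peroxidase, had 6.20 ± 1.345, or 2.88 without N2 9 and 6.79 without N2 2. The summed eosinophil list was 477, 107 and 105 CPM before TMM scaling in mature 1, 4 and 8.

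Altogether 1494 genes differed, 1074 higher and 420 lower in N2. The split was 822 higher and 593 lower with DESeq2 size factors, which moved the median log2 fold change of all genes from −0.36 to −0.68, and DESeq2 itself called 1488 higher and 2708 lower. With the run of library numbers as a factor 3550 genes were called, 2046 higher and 1504 lower. Leaving out N2 5 gave 988 genes and leaving out mature 4 gave 865. The 4 list calls ended without N2 2 (adjusted p = 0.0529 to 0.0597), N2 9 (0.0571 to 0.0578) or mature 4 (0.059 to 0.063). Those of interferon-stimulated genes (0.0731), heme synthesis (0.0524) and eosinophil markers (0.0524) also ended without mature 1.

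The comparison of eNeP with mature cells joins the ends of the series. Many primary granule, ribosome, replication and secretory pathway genes were higher in eNeP, and many receptor, late granule and interferon genes were higher in mature cells. MPO was at 35.5 ± 7.64 CPM in mature cells, a log2 fold change of 11.57 ± 1.2 (adjusted p = 6.96e-06, n = 3 each), or 9.45 without eNeP 82, and CTSG was higher by 11.82 ± 1.10, or 10.22 without eNeP 82. AZU1, azurocidin, had 0 counts in mature cells and was at least 383.9-fold higher in eNeP, a bound of 199.6 without eNeP 82, 233.9 without mature 1 and 240.2 without mature 8. ELANE, with 3 counts in mature cells, had a ratio of 4271 (counting interval 1461 to 20710, which covers counting error only). That ratio rested largely on eNeP 82, without which it was 1070 (366 to 5187). It was 2602 without mature 1, and without mature 8, which held all 3 counts, at least 2672. Of 12 azurophil genes 10 were higher (10 adjusted over the list alone), with a median of 10.47, or 9.29 with 1 gene without counts at its bound (camera adjusted p = 0.0431). The growth factor CLEC11A was at 5843 ± 2559 against 4.45 ± 1.465 CPM (10.36 ± 1.095; 9.62 without eNeP 82). LTF ran the other way, lower in eNeP by −2.42 ± 0.51 (−1.83 without mature 1), and of the 20 specific granule genes 11 were lower and 2 higher (12 and 4 adjusted over the list alone, median −2.52, camera adjusted p = 0.402).

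Of 74 ribosomal protein genes 62 were higher in eNeP and 0 lower (65 adjusted over the list alone, median 3.54, camera adjusted p = 0.236), as were 31 of 35 DNA replication genes (31 adjusted over the list alone, median 3.45, adjusted p = 0.122) and 19 of 30 mitosis genes (24 adjusted over the list alone, median 3.59, adjusted p = 0.213). So were 26 of 52 oxidative phosphorylation genes (32 adjusted over the list alone, median 1.59, adjusted p = 0.319) and 11 of 13 mitochondrially encoded transcripts (11 adjusted over the list alone, median 2.93, adjusted p = 0.213). NHP2, of the small nucleolar ribonucleoproteins, was higher by 6.78 ± 0.62, the replication licensing factor CDT1 by 6.33 and the ATP synthase subunit ATP5MC1 by 5.95 ± 0.64. Of 18 granulocyte-monocyte progenitor genes 13 were higher and 1 lower (13 and 1 adjusted over the list alone, median 6.06, adjusted p = 0.128), and of 25 endoplasmic reticulum folding and secretion genes 19 were higher and 1 lower (21 and 1 adjusted over the list alone, median 3.06, adjusted p = 0.0781), with the unfolded protein response factor XBP1 at 5.90 ± 0.60 (5.28 without eNeP 82). Heme synthesis was called as a list, 6 of 8 genes being higher (6 adjusted over the list alone, median 2.94, camera adjusted p = 0.0371), with UROS at 5.52 ± 0.60. MYC was higher by 4.6 ± 0.87 (5.53 without mature 8), MYB by 6.18 ± 0.71 (5.45 without eNeP 82) and CEBPE by 4.57 (3.90 without eNeP 11). TFRC was higher by 2.11 ± 0.56 (adjusted p = 0.0107), a call that ended without mature 4 (0.0581) and with only the 2 groups in the fit (0.0553). KIT was not called (2.27 ± 1.05, adjusted p = 0.124).

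FPR1 was at 2.05 ± 0.801 CPM in eNeP and 4701 ± 757 in mature cells (−11.16 ± 0.67, adjusted p = 4.99e-08; −11.76 without eNeP 82), and the interleukin-8 receptor CXCR1 at 0.159 ± 0.146 and 292 ± 61.55 CPM (−11.01 ± 0.96; −10.34 without eNeP 7 and −12.33 without eNeP 82). Of 26 receptors and effectors of mature neutrophils 24 were lower in eNeP (25 adjusted over the list alone, median −6.32, camera adjusted p = 0.0371), and of 16 gelatinase and secretory genes 14 (14 adjusted over the list alone, median −7.32, adjusted p = 0.0489). Of 18 late transcription factors 16 were lower and 1 higher (17 and 1 adjusted over the list alone, median −3.73, adjusted p = 0.0312), and of 18 chemotaxis receptors 14 were lower and 1 higher (14 and 1 adjusted over the list alone, median −4.59, adjusted p = 0.0371). The interferon-stimulated list had 14 of 20 genes lower (14 adjusted over the list alone, median −3.48, adjusted p = 0.0371). JUNB was lower by −6.27 ± 0.76 (−6.94 without mature 8), and the interferon-induced membrane protein IFITM1 by −8.79 ± 0.87 (−9.88 without eNeP 82). JUNB and FOS of the late transcription factors are also dissociation and stress response genes, a list that before TMM scaling summed to 939 to 2049 CPM in eNeP and 8081 to 27480 CPM in mature cells. Of its 15 tested members 6 were lower and 3 higher in eNeP (6 and 4 adjusted over the list alone, camera adjusted p = 0.648), with a median log2 fold change of 0.47 and a mean of −0.83, which differ in sign. Whether handling raised these genes in mature cells was not tested. The cyclin CCNG2, which is high in resting cells, was lower by −4.77 ± 0.55.

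This comparison called 3994 genes, 2334 higher and 1660 lower in eNeP, and no left-out library moved the number by over 1.5 times. The balance was not stable. It was 1776 higher and 1874 lower without mature 8, 1693 and 1700 with only the 2 groups in the fit, 2057 and 1929 with TMM without the abundant gene classes and 2124 and 1924 with DESeq2 size factors. The azurophil list call ended without eNeP 7 (0.0601), eNeP 11 (0.0707), mature 4 (0.063) or mature 8 (0.0789), and the late transcription factor call without eNeP 11 (0.0705) or mature 4 (0.059). The receptor call ended without eNeP 7 (0.0601), eNeP 11 (0.0705) or mature 4 (0.059). The gelatinase call (0.075, 0.0735, 0.0524 and 0.063) and those of chemotaxis receptors (0.0601, 0.0707, 0.052 and 0.063), interferon-stimulated genes (0.0601, 0.0707, 0.0536 and 0.059) and heme synthesis (0.0601, 0.0707, 0.0524 and 0.063) ended without eNeP 7, eNeP 11, mature 1 or mature 4. DESeq2 size factors ended the azurophil (0.0633) and gelatinase (0.0563) calls.

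**Figure D5:**
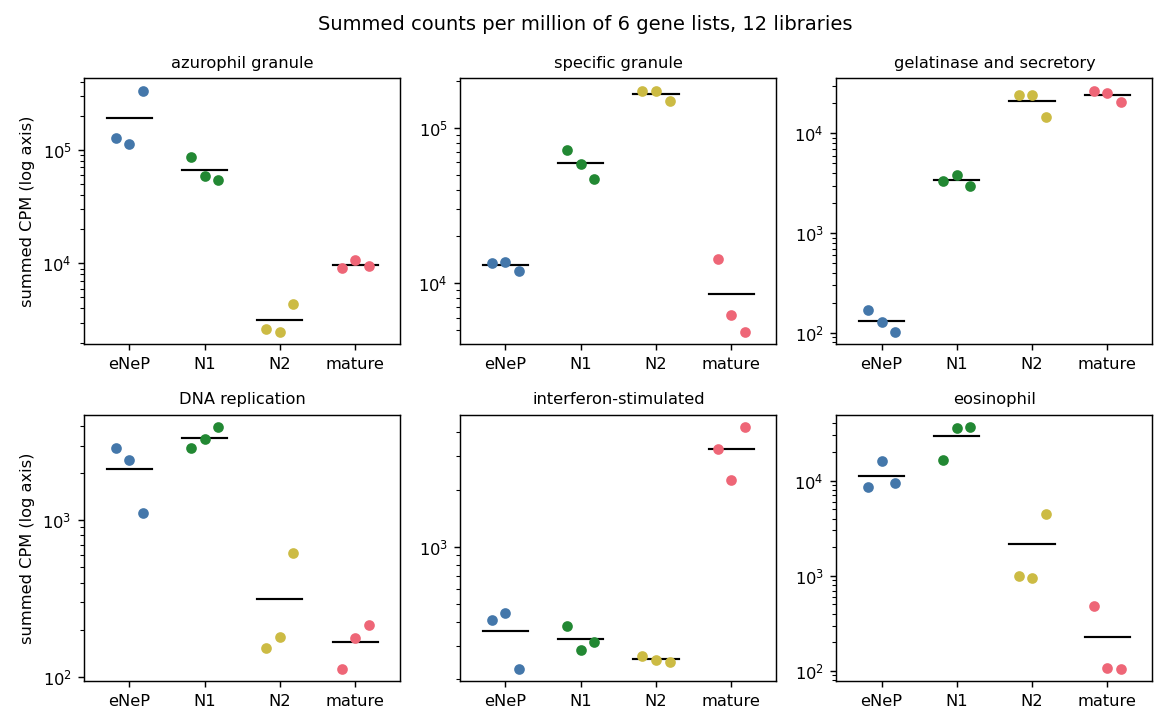
Summed CPM before TMM scaling (log axis) of the members of 6 gene lists in each of the 12 libraries, grouped by population, with a line at the mean of 3. The eosinophil list summed to 16540 to 36430 CPM in N1 and to 105 to 477 CPM in mature cells.

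Among all 4 populations 4019 genes (23.44% of 17145 tested) differed in the test over 3 coefficients. The highest mean of log CPM (prior count 2) of these genes fell in eNeP for 1248, in N1 for 909, in N2 for 642 and in mature cells for 1220. Over all 17145 tested genes it fell most often in mature cells (6455 genes, 37.65%), then in eNeP (4666), N1 (3179) and N2 (2845). Genes with single-library values that did not overlap between the groups made up 15.16% of those tested for eNeP with N1, 25.7% for N1 with N2, 33.65% for N2 with mature cells and 35.26% for eNeP with mature cells, where chance gives 10%. The test asks for any difference among the populations and not which of them is highest. The highest mean of MPO (adjusted p = 2.41e-06) and CTSG (5.33e-07) was in eNeP, that of BPI, which binds bacterial lipopolysaccharide, in N1 (4940 ± 861 CPM, 0.000284), that of LTF (3.69e-07) and MMP9 (8.4e-06) in N2, and that of ALPL (1.02e-06) in mature cells. The highest mean of MKI67 was in N1 (7.2e-05) and that of MYC in eNeP (24.96 ± 5.45 CPM, 0.000596). Several of these means were not separated from those of a neighbouring population. That holds between eNeP and N1 for MPO (adjusted p = 0.315), CTSG (0.142), BPI (0.224), MKI67 (0.653) and MYC (0.868), between N1 and N2 for BPI (0.191), and between N2 and mature cells for MMP9 (0.744). Before TMM scaling the T and NK cell list summed to 79.8 to 132 CPM in eNeP, 235 to 380 in N1, 14.3 to 53.5 in N2 and 32.9 to 63.0 in mature cells. Most of the N1 sum was CD4 (183 to 354 CPM after TMM scaling, whose factors in N1 ran from 1.07 to 1.206), while 11 of 12 tested members of the list had a higher log2 level in eNeP than in N1 (median 1.71), and 0 were called. The monocyte list, also before TMM scaling, summed to 160 to 661, 536 to 637, 74.5 to 341 and 302 to 463 CPM. Erythroid genes summed before TMM scaling to 82.4 to 316 CPM in eNeP, 40.0 to 140 in N1, 19.8 to 36.2 in N2 and 62.4 to 186 in mature cells. The stromal and endothelial list, which holds ALPL, summed before TMM scaling to 27.3 to 67.8, 42.5 to 80.0, 83.8 to 104 and 540 to 1369 CPM in the same order.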

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

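The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined, except the fits without both eNeP 82 and N1 3 and with a GC curve, which were chosen after the results were seen. Single genes were run under DESeq2, both other scalings, the run factor, the fit of only the 2 groups, each library left out and these later fits, and not under the other alternatives. There no direction of a named call was reversed, and 196 of 279 named gene calls kept their side of the threshold in every alternative that gave them a value, while 82 were lost without at least 1 library, 41 without both eNeP 82 and N1 3, 32 with the GC curve, 14 and 13 under the other scalings, 13 with only the 2 groups in the fit and 2 with the run factor. Some named genes had no value under DESeq2 or in the fit of only the 2 groups, and these were not counted as lost. Many named genes were chosen for the largest called changes, so their share kept does not describe all calls. Of all 32 calls of eNeP with N1, 10 (without eNeP 7) to 26 (without N1 10) were called again with a library left out. For N1 with N2 it was 358 (without N2 5) to 631 (without N2 9) of 817, and for N2 with mature cells 820 (without mature 4) to 1034 (without mature 1) of 1494. Calls gained numbered 4 with DESeq2 (CEACAM8 and ELANE in eNeP with N1, FCGR3A in N1 with N2, CD34 in N2 with mature cells), 2 with the run factor (FCGR3A in N1 with N2, MPO in N2 with mature cells), 2 with a library left out (FCGR3A in N1 with N2 without N2 9, CD34 in N2 with mature cells without N2 5) and 1 without both libraries (MPO in N2 with mature cells). Where fewer libraries entered, the fit had fewer residual degrees of freedom. For the other moved counts the cause was not tested. The 32 genes of eNeP with N1 became 82 with no filter on low counts, 67 with the run of library numbers as a factor, 15 with a minimum fold of 2, 222 with DESeq2, 14 without both eNeP 82 and N1 3 and 17 with the GC curve, with 32, 32, 32, 10 and 16 of the 32 shared with the fits without filter, with the run factor, with DESeq2, without both libraries and with the GC curve. The 817 genes of N1 with N2 became 1840 with the run factor, 387 with the minimum fold, 1379 with only the 2 groups, 2126 with DESeq2, 1352 with limma-voom and 379 without both libraries. The 1494 genes of N2 with mature cells became 3550 with the run factor, 677 with the minimum fold and 4196 with DESeq2, and the 4019 genes among populations 6419 with DESeq2. Leaving out each library in turn gave 11 (without eNeP 7) to 30 (without N1 10) genes for eNeP with N1, 368 (without N1 3) to 793 (without N2 9) for N1 with N2, 865 (without mature 4) to 1243 (without mature 1) for N2 with mature cells, 2913 to 3650 for eNeP with mature cells and 3177 to 4356 among populations. Besides the lowest, counts moved by over 1.5 times without eNeP 11 (19), eNeP 82 (14), N1 3 (21) and N1 6 (20) for eNeP with N1, without N1 6 (532), N2 2 (373) and N2 5 (389) for N1 with N2, and without N2 5 (988) for N2 with mature cells. DESeq2 size factors moved the median log2 fold change of all genes from 0.17 to 0.38 for eNeP with N1, from −0.36 to −0.68 for N2 with mature cells and from −0.03 to −0.17 for eNeP with mature cells, and TMM without abundant classes moved it from 0.38 to 0.23 for N1 with N2 and from −0.03 to −0.25 for eNeP with mature cells. The populations share no library number in the labels, so no pairing by number could be made. The numbers repeat the order mature, N2, N1 in 1 to 3, 4 to 6 and 8 to 10, with eNeP next at 7 and 11, so the fit with the run as a factor is a paired analysis if a run is a donor or day, which the labels do not say. In that fit eNeP 82 is alone in its run, so the factor takes up that library and comparisons with eNeP rest on eNeP 7 and 11. There the effect of pairing cannot be told from that of losing eNeP 82. Within the runs, deviations of 15 pairs of libraries had a mean correlation across genes, which are not independent replicates, of 0.209 (−0.109 to 0.548, 11 above 0), against −0.0808 in 39 other pairs (−0.4855 to 0.5838, 13 above 0). The highest value of all was in 1 of these other pairs, eNeP 82 with N1 6. Deviations sum to 0 within each population, so a positive mean in one kind of pair pulls the other kind down. Within the runs, the pairs of N1 with N2 had 0.202, 0.389 and 0.548 and those of N2 with mature cells 0.134, 0.214 and 0.163, while 4 of the 9 others were below 0. The order of the numbers and these values are hints of pairing, which the design does not state. The values may also follow the number of genes detected. The library with the most genes in each population was eNeP 82 (23105), N1 6 (22186), N2 5 (21154) and mature 4 (22360). Pairs among these had correlations from 0.2139 to 0.5838, also those with eNeP 82, which shares no run. Pairing and genes detected were not told apart. Depth limits the genes with few counts, and the shallowest library, eNeP 11, held 7055500 counts. The number of genes detected did not follow depth alone. It was 22360 in mature 4 with 7639071 counts, and 14845 in N2 2 with 19720162 counts.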

Other observations

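In this part the tests chosen only after the result was seen are those of the eosinophil pattern and, for eNeP with N1, those of scaling and of library eNeP 82. Glycolysis and cholesterol synthesis had members called both ways between eNeP and mature cells. Of 21 glycolysis genes 6 were higher in eNeP and 6 lower (7 and 6 adjusted over the list alone, median −0.28, camera adjusted p = 0.932). Glucose-6-phosphate isomerase, GPI, was at 1180 ± 886 against 47.95 ± 36.4 CPM (log2 fold change 4.62; 3.52 without eNeP 82 and 5.48 without mature 1), while the glucose transporter SLC2A3 was at 3.42 ± 3.56 against 980 ± 631 CPM (−8.19 ± 0.94; −9.47 without eNeP 11 and −7.56 without mature 1). SLC2A3 was also lower in N1 than in N2 (−5.125 ± 0.81, adjusted p = 0.00175), as was hexokinase 2 (HK2, −3.24 ± 0.56), and GPI was higher in N2 than in mature cells (4.35 ± 0.69; 5.25 without mature 1). Of 22 cholesterol synthesis genes 6 were higher and 4 lower in eNeP than in mature cells (6 and 4 adjusted over the list alone, median 0.53, camera adjusted p = 0.635). Of 7 NADPH oxidase genes 5 were lower in eNeP (5 adjusted over the list alone, median −2.21, camera adjusted p = 0.262, fry adjusted p = 0.00193), with NCF1, whose pseudogenes make its value uncertain, at −7.45 ± 0.80 (−8.15 without mature 8).

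Apoptosis regulators of opposite function and some genes of cell cycle exit were higher in mature cells than in eNeP. Of 18 apoptosis regulators 7 were lower and 1 higher in eNeP than in mature cells (7 and 1 adjusted over the list alone, median −1.59, camera adjusted p = 0.236). The survival protein BCL2A1 was at 1.84 ± 1.985 CPM in eNeP, 10.7 ± 7.61 in N1, 97.7 ± 13.9 in N2 and 491 ± 352 in mature cells (adjusted p = 1.66e-05 among the 4 populations, edgeR). The genes BBC3 (log2 fold change −3.645 ± 0.78; −4.30 without eNeP 11) and TNFSF10 (−4.96 ± 0.96; −6.77 without eNeP 11 and −4.34 without eNeP 7), which promote cell death, were lower in eNeP as well. The survival gene BCL2 ran the other way (3.155, adjusted p = 0.0297; 2.49 without eNeP 11 and 3.88 without mature 4). Its call ended without eNeP 11 (0.137), eNeP 82 (0.0512) or mature 8 (0.0862), under both other scalings (0.0524 and 0.0508) and with only the 2 groups in the fit (0.0683). Of 15 cell cycle exit genes 9 were lower and 2 higher in eNeP than in mature cells (10 and 2 adjusted over the list alone, median −2.86, camera adjusted p = 0.205), and TOB1, an antiproliferative gene, was lower in N1 than in N2 by −3.81 ± 0.62. Of 25 endoplasmic reticulum folding genes 10 were higher in N1 than in N2 and 0 lower (12 adjusted over the list alone, median 0.95, camera adjusted p = 0.205), with XBP1 at 3.215 ± 0.53 and the chaperone cofactor SDF2L1 at 3.42 ± 0.56.

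Eosinophil granule transcripts were abundant and uneven in N1, with PRG2 at 5936, 14140 and 16490 CPM and EPX at 835.4, 3413 and 5106 CPM in N1 3, 6 and 10, against 1944, 5320 and 1459 CPM of PRG2 in eNeP 7, 11 and 82. A candidate explanation is RNA of eosinophil-lineage cells in the sort, since the gates in the labels name CD16, CD71 and CD117 and no eosinophil antigen. Across libraries within populations the 12 list genes, of which RNASE2 and RNASE3 are also known from neutrophil precursors, moved together more than 62.33% of 10000 random lists matched on expression, a percentile between the bounds set for and against it. Of 11 relations of PRG2 deviations with those of the other list genes over 12 libraries, the highest were EPX (r = 0.878, p = 0.017, adjusted 0.0934; rho = 0.811, p = 0.0201, adjusted 0.11) and PRG3 (r = 0.761, p = 0.00617, adjusted 0.0679; rho = 0.804, p = 0.00694, adjusted 0.0764), with r = 0.852 and 0.697 without the 2 farthest libraries, against 0.191 for CLC and −0.707 for ALOX15, and 0 passed after adjustment (2-sided exact permutation within populations). A day, donor or batch shared by a run of library numbers is open as well. In CPM before TMM scaling, the library of numbers 8 to 11 had the highest summed list in 3 of 4 populations, with an exact probability of 0.1111. In eNeP that order depends on the scaling. There eNeP 11 summed to 16100 CPM (TMM factor 1.295) and eNeP 82 to 9344 CPM (0.6542), and with these factors applied eNeP 82 is the higher. The count of populations therefore cannot decide for or against a shared run. Neither explanation can be told from the other or from a biological one, which was not tested.

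The comparison of eNeP with N1 was one-sided, with 32 genes lower and 0 higher in eNeP (edgeR; 448 higher at an unadjusted p under 0.05, 65 with DESeq2, 7 with limma-voom, 7 with the run factor, 5 with no filter on low counts, 2 without N1 3 and 2 without both eNeP 82 and N1 3). Neither of the 2 other scalings removed the one-sidedness, since 0 genes were called higher under both, while the median of all genes moved by up to 0.2103. That move is small beside the smallest called difference of 2.49, so the test had little room to show scaling as the cause and does not exclude it. Lower depth of eNeP as the whole cause is argued against by thinning every library to the total of the shallowest, which left 26 genes lower and 1 higher of 13606 tested, all 26 among the 32. For spread added by eNeP 82, 735 genes were lower against 370 higher at an unadjusted p under 0.05 without that library, and 14 were called lower and 0 higher. Leaving it out also moved the median log2 fold change of all genes from 0.1711 to −0.03634. Spread and scaling cannot be told apart there, so that explanation stays open. Genes higher in eNeP at an unadjusted p under 0.05 had a median of 4.884 CPM and a median coefficient of variation of 0.7935, against 33.07 CPM and 0.5205 for those lower, so the one-sidedness may lie partly in scarcer and more variable genes, a hypothesis noticed and measured on the same data. The difference in CD117 that the sort names stays open and was not tested apart from these. For N1 3 the CD117 status rests on its title. There PRSS57 (912 CPM) and CTSG (16160 CPM) lay above N1 6 (75.65 and 4847) and N1 10 (98.97 and 2669), towards eNeP. KIT in N1 3 (3.207 CPM) was below N1 6 (3.341). DEFA4 (10980 CPM) and component 2 (−9.852) of N1 3 lay between N1 6 and N1 10. Whether CD117-positive cells entered N1 3 was not tested.

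In eNeP, ELANE, PRTN3 and AZU1 were far below CTSG, another serine protease of the azurophil granule, with CTSG 168.2 to 697.1 times ELANE, 659.1 to 1287 times PRTN3 and 1151 to 2386 times AZU1 in single libraries. Weaker recovery of GC-rich transcripts could lower them, since their GC content is 66.83%, 66.41% and 63.4% against 54.69% for CTSG. Among transcripts of similar length, 273 as GC-rich as these 3 genes had a median level in eNeP that differed from that of 258 with the GC content of CTSG by −0.4952 on the log2 scale (CTSG-like minus GC-rich), against a gap of 10.04. Levels of different genes mix expression with recovery, and those of the GC-rich transcripts had an interquartile range of 6.016. The difference therefore cannot decide on recovery of these 3 genes. PRSS57 (67.71% GC) and CLEC11A (67.72% GC) stood at 5183 ± 5548 and 5843 ± 2559 CPM in eNeP, so transcripts this GC-rich could reach high counts. Reads shared with overlapping genes are argued against, as 0 of the 3 genes overlap another annotated gene. The design names no group that bears on a ratio within eNeP, so no biological explanation was tested.

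Other splits of the same libraries were refitted for each count. For eNeP with N1 (32 genes), N1 with N2 (817), N2 with mature cells (1494) and eNeP with mature cells (3994), 1 of 10 splits, the real one, gave as many genes, the highest of the others gave 0, and 10 splits are too few for a share under 0.05. For the 4019 genes among the 4 populations, 1 of 100 divisions into 4 groups of 3, the real one, gave as many, and the highest of the others gave 4, so a chance division is excluded at a share under 0.05.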
